A study of Arabidopsis thaliana with 44 samples.

How the data were processed

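RNA of whole Arabidopsis thaliana seedlings and plants was measured on 44 Agilent arrays with 2 channels each. The samples formed 28 pools, from 4 genotypes on 7 days after sowing (4, 6, 10, 15, 20, 25 and 30). The genotypes were the accessions Col-0 and C24, each crossed to itself, and both directions of the cross between them, named Col-0 x C24 and C24 x Col-0 as in the labels. The labels do not say which name stands for the mother. Per the labels' protocols, plants of days 4 and 6 grew in dishes in a growth chamber and plants of days 10 to 30 in pots in a phytotron, both under long days. Also per the labels' protocols, plants were grown in 4 independent replicates and the extracted RNA was pooled for each genotype and time point.

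Each array set 1 pool in Cy5 against another in Cy3. In each genotype, 7 arrays closed a loop through the days (28 arrays), and on days 4, 10, 20 and 30 another 4 arrays closed a loop through the genotypes (16 arrays). A pool was thus hybridised 2 to 4 times. Repeated hybridisations of a pool are technical. Only 1 pool stood for each genotype and day, so p-values of comparisons averaged over days or genotypes measure the spread between pools of different days or genotypes. P-values of single days measure the technical spread alone.

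Spot intensity values were deposited as mean signals and local background medians per channel, read with Agilent Feature Extraction 10.1.1.1 per the file headers. Per the file headers, the processed intensity values were background-subtracted with a spatial detrend, multiplicatively detrended and dye-normalised by a linear and a LOWESS step, with surrogate values for dim spots. The deposited log10 ratios of Cy5 over Cy3 were computed from those processed signals per the file headers. The deposited series table held the same log10 ratios as each array's own file, with a largest difference of 0, so its scale and direction were known. The medians of its columns ran from 0 to 0.020, and no further centring was found. How the images were scanned beyond these headers is not given in the sources used here. Coordinates are those of the probes in the array design, build ath1:Jan2004 per the file headers. No genome sequence was used here, so the exon, intron or UTR position of a probe is not given.

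The mean signals were corrected with normexp (offset 50) and normalised within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. No scaling between arrays was applied. Spots marked by the scanner software as uneven or as population outliers were left out, between 4 and 399 per array (median 10). Saturated spots were kept; at most 2 spots of an array were saturated in Cy5 and 0 in Cy3. Tables were handled with the R package data.table (version 1.17.8) and Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

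Of 43603 probes, 37540 named 1 locus in the files, 873 named several and 5190 named none; only the first kind was tested. The files held 28479 loci, of which 28074 (98.6%) matched a locus in the reference table of assembly TAIR10.1, used for names only. A probe was tested if it was well above background in every measurement of at least 1 pool, which left 31312 probes. Each gene was represented by its tested probe of highest mean intensity, which gave 23318 genes, 9500 of them with a symbol. Of these, 6219 had more than 1 tested probe. Neither of the 2 probes of FT was well above background in every measurement of any pool, so FT was not tested.

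Per gene, the log2 ratios were fitted on the 28 pools plus a dye term (16 residual degrees of freedom). The pool values then entered a limma fit on genotype and day (18 residual degrees of freedom), with empirical Bayes moderation and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05. The comparisons were Col-0 minus C24, the mean of both hybrids minus the midparent on the log2 scale, Col-0 x C24 minus C24 x Col-0, day 30 minus day 4 and the 6 steps between consecutive days. Trends added a slope per genotype over days, given per 10 days (15 residual degrees of freedom). Single days were tested in the array fit.

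The text names genes by a rule. For each of the 4 main comparisons it took the 8 largest folds per direction among genes that passed, were well above background in every pool compared, kept their sign on each day or in each genotype and had a symbol. It added up to 3 members of each gene list that passed, with the largest change among those that passed, and 3 genes per direction for each trend. FLC, FRI and SOC1 were given for parents and hybrids in any case. Members of lists in the steps, and other genes said to be so, were named after their values were seen. For parents, up to 4 genes per direction were to be named that lay below background in every pool of 1 parent and above it in every pool of the other. On every array of the dim parent, 0 such genes were found; counted after that result, a wider reading with some array below background in every pool of the dim parent gave 35 genes brighter in Col-0 and 5 brighter in C24, and none was named from it.

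The 23 gene lists held 460 members, of which 13 were left out because the reference names the locus differently, and 435 of the other 447 were tested. The lists were light harvesting and photosystem proteins, chlorophyll biosynthesis, cytosolic ribosomal proteins, cell cycle and DNA replication, cell wall expansion, auxin response and phytochrome-interacting factor targets, floral repressors, floral promoters, floral organ markers, root markers, seed storage and maturation, storage lipid mobilisation, salicylic acid and defence, jasmonate, glucosinolates, flavonoids and anthocyanins, the circadian clock, leaf senescence, cold with drought and abscisic acid, heat shock proteins, DNA methylation and small RNA, phosphate starvation, and nitrate uptake with nitrogen assimilation. Each was tested with limma's cameraPR, two-sided, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists. Grouping, tests, lists, the naming rule and most of the alternatives were fixed before the data were examined.

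The steps were tested on simulated data for all 23318 genes with 200 changed, 100 by 0.5 and 100 by 1 on the log2 scale. For Col-0 minus C24, 82 and 97 of each 100 were recovered but 55.5% of calls were false. For hybrids minus midparent, 94 and 98 were recovered and 71.6% of calls were false. For day 30 minus day 4, 63 and 92 were recovered and 5.49% of calls were false. In number, the false calls were 223, 483 and 9 in these comparisons. The false share depends on the share of changed genes, 200 of 23318 here, so the percentages do not carry over to the real counts. The pools of a loop share the error of its arrays, which the planned error term of the genotype comparisons leaves out. An error term that carries the array error through the loop was therefore added after the data were seen. With it, parents recovered 67 and 93 with 3.03% false calls, hybrids 87 and 97 with 5.64%, and day 30 minus day 4 recovered 62 and 91 with 4.97%. Its total counts stand beside those of the genotype comparisons. Also after the data were seen, list means were taken for each genotype comparison of 1 day that the arrays of 1 slide gave on their own, with the fitted dye term taken off.

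The alternatives fixed then were Agilent's processed signals, no background subtraction, median centring, Aquantile scaling, the series table, no filter or a strict filter on dim probes, outlier spots kept, the mean of all probes, no dye term, slide as a fixed or random block, terms for the 7 batches of cRNA synthesis, array quality weights, pools weighted by hybridisations, the array error alone, same-day arrays or time loops alone, days in pots only, a 2-fold minimum, a trended robust prior, and leaving out each array, day or genotype. Added after the data were seen were leaving out the 4 arrays of highest signal, the C24 pool of day 10, the pair of arrays with Col-0 x C24 of day 30 in Cy3, and all of these together; 2 midparent fits of daily differences, on the linear and the log2 scale; and the array error carried through the loop. The number of the arrays limits the precision. Counts and list calls with the slide as a block used the planned error, except on single days. Median Cy3 signals ran from 146.5 to 1220.1 (median 274.4) and median Cy5 signals from 303.5 to 3778.9 (median 556) per array.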

Results

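The series followed gene expression in growing Arabidopsis thaliana, a small rosette plant, in the accessions Col-0 and C24 and in both directions of the cross between them. It compared the parents with each other, the hybrids with the parents, the hybrids with each other, and successive ages. The data were 44 arrays with 2 colours of 28 pools, 7 pools per genotype, from day 4 to day 30 after sowing. Between 58.7% and 99.9% of spots per array were well above background in Cy3 (median 69.3%), and between 73.5% and 100% in Cy5 (median 84.7%). The array of the C24 pools of days 25 and 20, that of the Col-0 and C24 pools of day 4, that of the Col-0 x C24 pools of days 25 and 20, and that of the Col-0 pools of days 4 and 30 had the highest signals. The pools were separated first by age and then by genotype. The first component held 33.7% of the variance, of which 94.0% lay between days. The third held 15.6%, of which 71.2% lay between genotypes. Errors given below are standard errors, over 7 days for genotype comparisons and over 4 genotypes for comparisons of days.

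**Figure D1:**
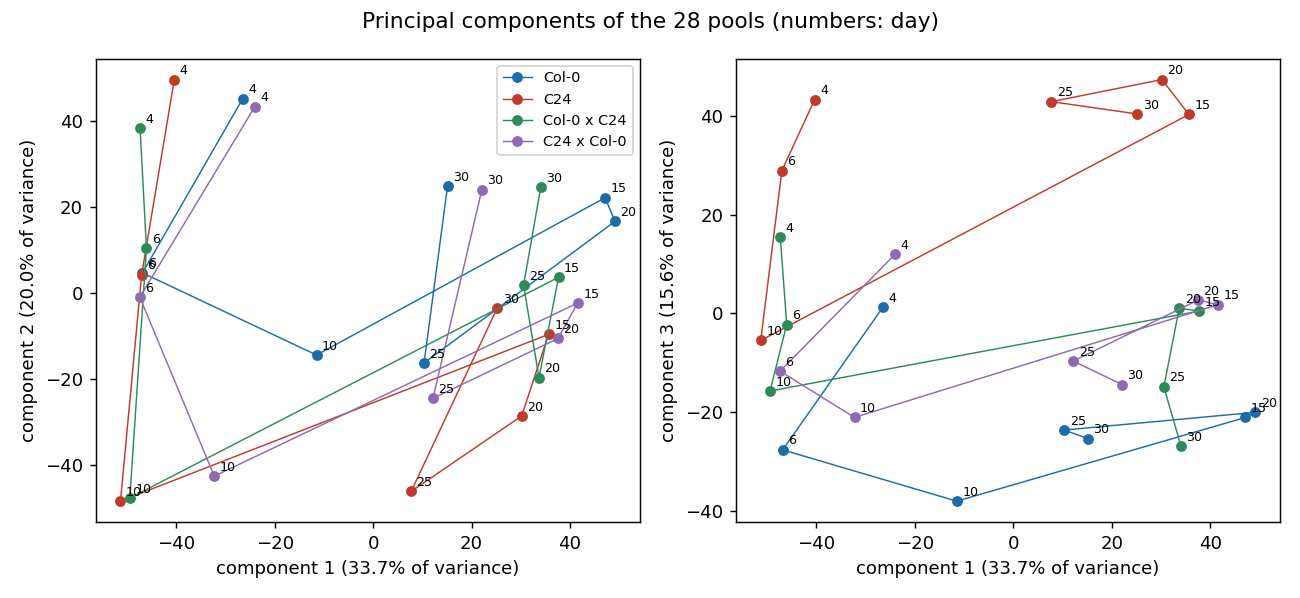
Scores (no unit) of the 28 pools on the second and the third principal component of log2 expression against the first, each point 1 pool numbered by its day after sowing, with a colour and a line through the days for each genotype. The first component held 33.7% of the variance and the second 20.0%, of which 94.0% and 79.7% lay between days, and the third, with 71.2% between genotypes, set C24 apart from Col-0 on most days.

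To ask how the parents differed, Col-0 was compared with C24 over the 7 days. Genes of the response to cold, drought and abscisic acid were higher in Col-0, with a list median of 0.99 on the log2 scale (adjusted p = 0.542 with an estimated correlation). In this list 13 of 18 genes rose and 0 fell, such as GOLS3, an enzyme of raffinose synthesis, by 3.05 (SE 0.46), RD29A by 2.76 (SE 0.38) and KIN2 by 2.45 (SE 0.30). Flavonoid and anthocyanin genes were also higher in Col-0, with 14 of 18 risen and 0 fallen and a median of 0.87 (adjusted p = 0.988 with an estimated correlation). Among them the regulator PAP1 rose by 2.41 (SE 0.40), the enzyme gene DFR by 2.34 (SE 0.40) and the transporter gene TT19 by 2.01 (SE 0.35). Genes of salicylic acid signalling and defence were lower in Col-0, with 22 of 24 fallen and 0 risen and a median of −1.11 (adjusted p = 0.878 with an estimated correlation). Among these the pathogenesis-related genes PR2 (−2.74, SE 0.46) and PR5 (−1.86, SE 0.30) were each lower on 6 of 7 days, and the transcription factor gene WRKY38 fell by 2.11 (SE 0.41).

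The adjusted p of these 3 lists was 1.98e-05, 0.000230 and 9.27e-08 at the preset correlation. The count adjusted over the list alone was 13 cold and 16 flavonoid genes risen and 22 salicylic acid genes fallen. With the array error carried through the loop 9, 12 and 19 of them passed over all genes. With the slide as a fixed block the mean shifts were 1.26, 1.18 and −1.22, against 1.18, 1.06 and −1.18 without it. Within a slide the parents could be compared on single arrays alone, without a test, on days 4, 10, 20 and 30. In that order the list means there were −0.03, 1.18, 1.56 and 1.92 for cold, −0.11, 1.19, 1.82 and 0.95 for flavonoid and −0.12, −1.22, −2.16 and −1.52 for salicylic acid genes. The array of day 4 had the highest signals of all arrays and the largest residual SD (0.263). Over 282 genes chosen as higher in Col-0 on days 20 and 30, its median was 0.31, while the fitted pools of that day stood at 0.19 in Col-0 and −1.14 in C24. Its means near 0 therefore did not show that the parents were alike on day 4. The array of day 10 carried a C24 pool whose median over these genes was −0.35, against −1.21 in C24 on day 6 and −1.12 on day 15.

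Single genes differed more. SADHU1-1, of a family of retroposons, was higher in Col-0 by 5.08 (SE 0.42, adjusted p = 9.91e-09; chromosome 2, 4013212 to 4013271). ESP, which directs glucosinolate breakdown towards nitriles, was lower in Col-0 (−5.67, SE 0.48, adjusted p = 1.44e-08; chromosome 1, 20174515 to 20174574). ESM1, which favours isothiocyanates in the same breakdown, was higher in Col-0 by 2.87 (SE 0.38; chromosome 3, 4731452 to 4731511). Others higher in Col-0 were ECS1, a cell wall protein gene (3.55, SE 0.33), CP12-2, a regulator of Calvin cycle enzymes (3.18, SE 0.23), Sadhu4-2 (3.14, SE 0.25), the serine carboxypeptidase-like gene scpl42 (3.00, SE 0.23) and the metal-transporting ATPase gene HMA1 (2.74, SE 0.19). Others lower in Col-0 were IGMT2, an indole glucosinolate methyltransferase gene (−3.05, SE 0.42), MRD1 (−2.87, SE 0.28), SADHU3-2 (−2.66, SE 0.19), the arabinogalactan protein gene FLA17 (−2.54, SE 0.20), the sterol glucosyltransferase gene SGT (−2.42, SE 0.15) and the plastid glucose-6-phosphate dehydrogenase gene G6PD4 (−2.27, SE 0.20). Each of these kept its sign on 7 of 7 days. The probes lie on the array design's build ath1:Jan2004.

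The floral repressor gene FLC was lower in Col-0 (−2.68, SE 0.31, adjusted p = 1.13e-06; chromosome 5, 3173781 to 3174832), and its other probes gave −2.63 and −2.32. FRI, an activator of FLC, was lower by less (−0.37, SE 0.04, adjusted p = 1.83e-06), and SOC1, a floral integrator repressed by FLC, was higher by 0.93 (SE 0.25, adjusted p = 0.00727). Of 23318 genes, 7981 differed between the parents, with 4094 higher and 3887 lower in Col-0; by at least 2-fold, 445 were higher and 284 lower. With the array error carried through the loop, 4888 passed (2515 higher and 2373 lower), the call of SOC1 was lost and the 16 genes with the largest folds kept theirs. The batches of cRNA synthesis largely followed the genotype in each colour, so both can hardly be told apart. With terms for them and the array error carried, 2444 passed, at 6.13 times the array variance. With the slide as a fixed block 4898 passed, with SADHU1-1 at 5.50, ESP at −5.55, FLC at −2.64 and SOC1 at 1.09. With median centring in place of loess 64.9% of the calls were higher in Col-0, against 51.3%.

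To ask whether the hybrids departed from the mean of their parents, both hybrids together were compared with the midparent. ESM1 was higher in the hybrids by 1.55 (SE 0.27, adjusted p = 0.00365) and was the only gene named by the rule that also passed with the array error carried through the loop. Under that error 8 genes passed, 8 higher and 0 lower, and with terms for the batches of cRNA synthesis added limma called 0 (1396 at an unadjusted p under 0.05); chosen after their values were seen, the other 7 were RPS15AD, a ribosomal protein gene (1.91, SE 0.30), AT5G52420 (1.80, SE 0.28), AT1G60010 (1.63, SE 0.25), AT5G42825 (1.51, SE 0.21), AT5G45490 (0.87, SE 0.12), AT5G34830 (0.58, SE 0.07) and AT5G38005 (0.52, SE 0.05). Against the linear midparent these 7 stood at 0.37, 0.38, 0.46, 0.53, 0.31, 0.56 and 0.46 and ESM1 at 0.82 (adjusted p = 0.136), and none passed; with a strict filter on dim probes RPS15AD stood at −0.12. By the planned error, ECS1 (1.39, SE 0.23), CP12-2 (1.15, SE 0.16), scpl42 (0.98, SE 0.16), the downy mildew resistance gene RPP13 (0.87, SE 0.14) and the NADH kinase gene NADK3 (0.76, SE 0.17) were higher too, with ECS1 at 0.46, CP12-2 at 0.38, scpl42 at 0.29 and RPP13 at 0.34 against the linear midparent. So were bZIP6 (0.34) and the cadmium tolerance gene CDT1 (0.32). GPT2, a glucose-6-phosphate translocator of plastids, was lower (−1.08, SE 0.16, adjusted p = 0.00219), as were the glutathione transferase gene GSTF6 (−0.90, SE 0.19), the nitrate transporter gene NRT1.7 (−0.47), the chaperone gene Hsp70-2 (−0.47) and the glycosyltransferase gene UGT87A2 (−0.46).

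Salicylic acid and defence genes were lower in the hybrids as a list, with a median of −0.33 (adjusted p = 1.48e-07, and adjusted p = 0.786 with an estimated correlation); 2 of 24 fell, PBS3 (−0.89, SE 0.16) and ICS1 (−0.56, SE 0.12), both of salicylic acid synthesis, and 22 did not pass. The test adjusted over the list alone had 9 fallen and 0 risen. Another 8 lists passed with small medians: ribosomal proteins (−0.09), storage lipid mobilisation (−0.11), cell cycle (−0.06), chlorophyll biosynthesis (−0.08), the clock (−0.12), leaf senescence (−0.05) and flavonoids (−0.09) lower, and jasmonate (0.24) higher. None of the 8 passed with an estimated correlation (adjusted p = 0.789 for flavonoids and adjusted p = 0.786 for the others). Of these, 1 ribosomal gene (RPS6A, −0.30) and 1 senescence gene (BGLU30, −1.15) fell, and adjusted over the list alone 3 ribosomal, 4 senescence and 1 clock gene fell. FLC was higher in the hybrids by 1.12 (SE 0.22, adjusted p = 0.0103) and SOC1 lower (−0.80, SE 0.18, adjusted p = 0.0223), while FRI was at −0.03 (adjusted p = 0.695). Neither FLC nor SOC1 passed with the array error carried through the loop (adjusted p = 0.164 and 0.787), and FLC stood at 0.55 against the linear midparent (adjusted p = 0.315). The excess of FLC was not steady over days. On day 20 Col-0 x C24 stood at 0.06 and C24 x Col-0 at 0.45, against −3.38 in Col-0 and 0.13 in C24. On day 25 the same pools stood at −0.63 and 0.28, against −0.75 and 0.52. On day 30 they stood at −1.26 and −0.07, against −2.52 and 1.05, so on both days the mean of the hybrids lay near the midparent. On day 30, C24 x Col-0 alone lay nearer to C24 than to Col-0. Both days rest on pools that stood apart. In Col-0 FLC was at −0.75 on day 25, far above days 20 and 30. Over genes higher in Col-0, the Col-0 x C24 pool of day 30 stood at 0.82, against 0.78 in Col-0. A loss of the excess with age is therefore not shown.

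On simulated data the planned error had given 483 false calls for hybrids minus midparent. By that error 488 genes differed from the midparent here, 295 higher and 193 lower, so their number cannot be told from false calls. By at least 2-fold, 34 were higher and 2 lower. Of these 36, 34 belonged to genes whose parents differed by more than 2 on the log2 scale, and their median departure was 1.26 from the log2 midparent and 0.38 from the linear midparent. With limma on daily differences from the linear midparent 0 genes passed, with 3740 at an unadjusted p under 0.05 and 71 passing on the log2 scale in the same fit. With the slide as a fixed block 2640 genes passed, the calls of NADK3 (0.86), SOC1 (−0.50), NRT1.7 (−0.54) and FLC (0.65) were lost, and the salicylic acid list had a mean of −0.40, against −0.37. The slide block was tested with the planned error, which leaves out the array error shared through the loop. Its 2640 calls are therefore no firmer than the 488. In that block the clock, flavonoid, jasmonate and senescence lists lost their calls, at means of −0.11, −0.19, 0.22 and −0.26. Within 1 slide both hybrids could be set against the midparent on day 10 alone, without a test. The C24 pool of that day, which stood nearer to Col-0 than C24 did on days 6 and 15, was part of this. There the list means were −0.14 for salicylic acid, −0.24 for clock, −0.26 for flavonoid, −0.01 for chlorophyll and 0.94 for jasmonate genes, but 0.06, 0.10, 0.11 and 0.03 for cell cycle, ribosomal, senescence and storage lipid genes. With median centring 79.2% of calls were higher in the hybrids, with days in pots alone 47.2% of 197, and without the 4 arrays of highest signal 71.1% of 304, against 60.5%.

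The hybrids were then compared with each other. The 4 genes that differed were all named after their values were seen. The chloroplast-encoded ATCG00190 was lower in Col-0 x C24 than in C24 x Col-0 (−1.43, SE 0.14, adjusted p = 3.97e-05), as were the chloroplast-encoded ATCG00440 (−0.80, SE 0.12, adjusted p = 0.00693) and the mitochondrion-encoded ATMG00650 (−0.65, SE 0.07, adjusted p = 0.000290). AT2G07811 was higher (1.03, SE 0.17, adjusted p = 0.0337) but was above background in 7 of 14 pools. Each kept its sign on 7 of 7 days. With the array error carried through the loop only ATCG00190 passed. With terms for the batches of cRNA synthesis, which largely followed the genotype, 8450 genes passed, but 0 by limma with that error carried as well (2228 at an unadjusted p under 0.05). In the slide block 2 genes passed, with ATMG00650 at −0.89 and the calls of ATCG00190 (−1.39), ATCG00440 (−1.43) and AT2G07811 (0.90) lost. With Agilent's processed signals 37.5% of 8 calls were higher, and without background subtraction 40% of 5, against 25%.

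As lists, cell cycle genes (median 0.09), ribosomal protein genes (0.07) and auxin genes (0.18) were higher in Col-0 x C24, and glucosinolate (−0.25), jasmonate (−0.23) and cold (−0.19) genes lower. Each of the 6 lists had adjusted p = 0.954 with an estimated correlation. Median centring shifted the median of all genes by −0.16 and turned the cell cycle and ribosomal lists, to means of −0.12 and −0.28. None of their members passed over all genes, and adjusted over the list alone 2 jasmonate genes fell. The lowest adjusted p at the preset correlation was 0.000392, for the cell cycle. With same-day arrays alone the cell cycle list turned to a mean of −0.021. Without the array of both hybrids of day 20 the jasmonate list turned to a mean of 0.0047. In the slide block cell cycle (0.31), ribosomal (0.31), cold (−0.57) and jasmonate (−0.58) genes kept their calls by their means, and auxin (0.04) and glucosinolate (−0.17) genes did not. On single arrays of days 4, 10, 20 and 30, each within a slide and without a test, cell cycle means were −0.19, −0.08, −0.08 and 0.11 and ribosomal means −0.10, −0.0045, −0.08 and 0.24, below 0 on 3 of 4 days. There auxin genes stood at 0.03, 0.85, 0.17 and −0.03, glucosinolate genes at −0.12, −0.71, −0.20 and −0.25, jasmonate genes at 0.04, −0.51, −0.45 and 0.02 and cold genes at 0.20, −0.80, −0.36 and 0.19.

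To follow the change with age, day 30 was compared with day 4 over the 4 genotypes. Glucosinolate genes rose, 20 of 29 with 0 fallen and a list median of 1.75; MAM1 (5.31, SE 0.32), CYP83A1 (5.29, SE 0.35), CYP79F1 (4.78, SE 0.45) and BCAT4 (4.47, SE 0.27) make glucosinolates from methionine. Cold and drought genes rose, 11 of 18 with 0 fallen and a median of 1.76, such as COR15A (5.88, SE 0.35), COR15B (5.40, SE 0.30), KIN2 (5.34, SE 0.40) and KIN1 (4.85, SE 0.37). The glucosidase gene BGLU18, which frees abscisic acid from its conjugate, rose by 6.15 (SE 0.37, adjusted p = 2.52e-10; chromosome 1, 19521688 to 19521746). PYK10, the main glucosidase of the endoplasmic reticulum bodies of roots and seedlings, was lower (−5.09, SE 0.27, adjusted p = 4.39e-11; chromosome 3, 2840483 to 2840512). So were the PYK10-binding lectin gene PBP1 (−4.30, SE 0.22), the lectin-like JAL34 (−3.82, SE 0.24) and JAL33 (−3.27, SE 0.35) and NAI2 (−2.88, SE 0.23), whose product lies in these bodies. Also lower were the protease gene CP1 (−3.93, SE 0.34), the trypsin inhibitor gene KTI1 (−3.14, SE 0.67) and the clock-related RVE2 (−3.35, SE 0.31).

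The glucosinolate and cold lists passed at an adjusted p of 1.49e-21 and 2.87e-11, and also with an estimated correlation (adjusted p = 0.000289 and 0.0105). Of their genes 21 and 11 rose when adjusted over the list alone. The other 11 lists that passed lost their call there, and what follows holds at the preset correlation. Floral promoters rose, 7 of 12 with 0 fallen, with AGL24 at 2.33 (SE 0.24), SOC1 at 1.81 (SE 0.34) and SPL3 at 1.38 (adjusted p = 0.135 with an estimated correlation). Jasmonate genes rose, 7 of 21 with 0 fallen, with the vegetative storage protein genes VSP2 at 5.24 (SE 0.53) and VSP1 at 4.90 and with CORI3 at 4.23 (adjusted p = 0.224 with an estimated correlation). Flavonoid genes rose, 10 of 18 with 0 fallen, with DFR at 4.55 (SE 0.53), TT19 at 3.56 and UF3GT at 3.00 (adjusted p = 0.418 with an estimated correlation). Salicylic acid genes rose, 8 of 24 with 0 fallen, with PR5 at 2.75 (SE 0.40), PR2 at 2.68 (SE 0.60) and WRKY54 at 2.18, and auxin genes, 8 of 25 risen and 1 fallen, with PIF4 at 2.68 (SE 0.18), PIF5 at 1.63 and HB-2 at 1.39 (adjusted p = 0.589 for each with an estimated correlation). DNA methylation and small RNA genes were 8 risen and 2 fallen of 20, with ROS1 at 1.46, MET1 at −0.63 and DCL4 at 0.38 (adjusted p = 0.224 with an estimated correlation). Light harvesting genes were 23 risen and 4 fallen of 37, with LHCB2.2 at 2.75 (SE 0.29), LHCB2.3 at 2.74 and LHCB4.2 at 2.18 and with the photosystem gene PSAL (−0.44) and the Rubisco small subunit genes RBCS1B (−1.15), RBCS2B (−0.52) and RBCS3B (−0.95) fallen, these 4 named after their values were seen; their mean was 0.55 and turned to −0.42 with median centring (adjusted p = 0.253 with an estimated correlation).

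Genes of storage lipid mobilisation fell, 8 of 16 with 0 risen, with the glyoxylate cycle genes ICL (−5.30, SE 0.45) and MLS (−3.28, SE 0.47) and with ACX2 (−1.25) (adjusted p = 0.253 with an estimated correlation). Nitrate genes fell, 7 of 14 with 0 risen, with NRT1.1 (−2.11, SE 0.11), UPM1 (−1.61) and NIA1 (−1.50) (adjusted p = 0.135 with an estimated correlation). Root markers fell, 15 of 21 with 0 risen, with PYK10 (−5.09), NRT2.1 (−2.63) and PHT1;1 (−2.57) (adjusted p = 0.130 with an estimated correlation). Seed storage genes fell, 9 of 13 with 0 risen, with EM6 (−1.83, SE 0.47), SESA5 (−1.22) and PER1 (−1.21) (adjusted p = 0.360 with an estimated correlation). The counts that moved when adjusted over the list alone were 24 light harvesting, 11 flavonoid and 10 DNA methylation genes risen. No call was made for heat shock proteins (adjusted p = 0.176), floral organ markers (0.789), floral repressors (0.375), leaf senescence (0.132), phosphate starvation (0.375), the cell cycle (0.726), cell wall expansion (0.0596), chlorophyll biosynthesis (0.595), the clock (0.789) or ribosomal proteins (0.954).

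In all, 7935 genes differed between day 30 and day 4, 4192 risen and 3743 fallen, with 614 risen and 579 fallen by at least 2-fold. With the slide as a fixed block 2804 passed; BGLU18 was at 6.19 and PYK10 at −5.44, the glucosinolate and cold lists had means of 1.85 and 1.97, against 1.99 and 1.97, and HB-2 (1.27), DCL4 (0.29), NIA1 (−1.55), EM6 (−1.79), SESA5 (−0.91), PER1 (−1.10), PSAL (−0.42) and RBCS2B (−0.59) lost their calls. In that block light harvesting (0.60), jasmonate (1.27), flavonoid (1.23), salicylic acid (0.87), auxin (0.36), floral promoter (0.66), root (−0.88), nitrate (−0.53) and storage lipid (−0.82) genes kept theirs by their means, and DNA methylation (0.04) and seed storage (−0.59) genes did not. With median centring 31.4% of the calls had risen, against 52.8%. Plants of days 4 and 6 grew in dishes and all others in pots, so age and growth conditions cannot be told apart in this comparison. The root list was set up as markers of another tissue. Whether the share of root in the material changed was not tested.

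Successive days were compared to place these changes; the list members named for these steps had the largest changes and were picked after their values were seen. In order of age 12, 10, 10, 6, 11 and 9 lists passed in the 6 steps, and only some of them are described. Between days 4 and 6, all 21 ribosomal protein genes fell, such as RPS6A (−0.93, SE 0.14) and RPL23AB (−0.85, SE 0.16) (adjusted p = 0.211 with an estimated correlation), and 10 of 28 cell cycle genes fell with 0 risen, such as PCNA1 (−0.64, SE 0.18) and MCM3 (−0.51) (adjusted p = 0.470 with an estimated correlation). Root markers fell with them, 9 of 21 with 0 risen and a mean of −0.45, also −0.45 in the slide block (adjusted p = 0.432 with an estimated correlation). Light harvesting genes rose, 27 of 37 with 3 fallen, such as LHCB2.2 (1.73, SE 0.29) and LHCB1.4 (1.52, SE 0.24), and clock genes rose, 11 of 19 with 0 fallen, such as PRR5 (1.53, SE 0.30), PRR7 (1.15, SE 0.18) and LUX (1.12, SE 0.19) (adjusted p = 0.211 for each with an estimated correlation). The adjusted p was 1.20e-15 for ribosomal, 5.92e-13 for light harvesting and 7.74e-05 for clock and cell cycle genes. When adjusted over the list alone, 17 cell cycle genes and 10 root markers fell, and 28 light harvesting genes rose and 4 fell. In the slide block the list means were −0.73, −0.49, 0.60 and 0.54 for ribosomal, cell cycle, light harvesting and clock genes, against −0.63, −0.32, 0.56 and 0.56, and PCNA1 (−0.89) and MCM3 (−0.63) lost their calls.

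Between days 6 and 10, the step from dishes to pots, 10 lists passed, 6 of them also with an estimated correlation. Cold and drought genes rose, 12 of 18 with 0 fallen (adjusted p = 0.000165 with an estimated correlation), such as COR15B (3.85, SE 0.30) and KIN2 (3.41). Genes of phosphate starvation rose, 9 of 12 with 0 fallen (adjusted p = 0.00448 with an estimated correlation), such as PS2 (2.79, SE 0.30), the non-coding IPS1 (2.13, SE 0.13) and SQD2 (1.29). Salicylic acid genes rose, 21 of 24 with 0 fallen, and jasmonate genes rose, 15 of 21 with 0 fallen (adjusted p = 0.0448 for each with an estimated correlation), with the camalexin gene PAD3 at 2.60 (SE 0.34), SARD1 at 2.36, VSP2 at 3.39 (SE 0.53) and CORI3 at 2.72 (SE 0.35). Glucosinolate genes rose, 16 of 29 with 0 fallen, such as the myrosinase gene TGG2 (2.50, SE 0.24) and MAM1 (2.05), and nitrate genes fell, 7 of 14 with 0 risen, such as NIA1 (−1.96, SE 0.53) and NRT1.1 (−1.28, SE 0.12) (adjusted p = 0.00993 for each with an estimated correlation). Root markers fell too, 5 of 21 with a mean of −0.24 (adjusted p = 0.489 with an estimated correlation), as did seed storage genes, 2 of 13 with a mean of −0.40 (adjusted p = 0.40 with an estimated correlation). The slide block gave list means of 2.08 for cold, 1.26 for phosphate, 1.64 for salicylic acid, 1.63 for jasmonate, 0.97 for glucosinolate, −0.66 for nitrate, −0.28 for root and −0.60 for seed storage genes, and none of these lists lost its call. Here 13 cold, 22 salicylic acid and 20 glucosinolate genes rose and 8 nitrate, 6 root and 4 seed storage genes fell, adjusted over the list alone.

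Between days 10 and 15 the phosphate genes fell, all 12 of them, such as SRG3 (−3.09, SE 0.32), PS2 (−2.62, SE 0.30) and IPS1 (−2.17, SE 0.13) (adjusted p = 0.120 with an estimated correlation). Root markers fell too, 6 of 21 with 0 risen and a mean of −0.48, a call lost in the slide block at −0.50 (adjusted p = 0.738 with an estimated correlation). Auxin genes fell, 20 of 25 with 0 risen, such as IAA29 (−4.11, SE 0.50) and GH3.5, which conjugates auxin (−3.20, SE 0.28) (adjusted p = 0.401 with an estimated correlation). The auxin list had passed as higher between days 6 and 10 at the preset correlation, with a mean of 1.35 in the slide block. Its fall thus set out from a raised level, in day 10 pools that both steps share. All 21 ribosomal protein genes rose, such as RPL23AB (1.28, SE 0.16) (adjusted p = 0.228 with an estimated correlation), and 13 of 18 flavonoid genes rose with 0 fallen, such as UF3GT (3.14, SE 0.54), TT19 (3.07, SE 0.47) and DFR (3.03, SE 0.53) (adjusted p = 0.433 with an estimated correlation). In this step 24 auxin genes and 6 root markers fell, and 15 flavonoid genes rose and 1 fell, adjusted over the list alone. Between days 15 and 20 cell cycle genes fell, 19 of 28 with 0 risen, such as the cytokinesis genes HIK (−0.81, SE 0.16) and KN (−0.75, SE 0.16) and the cyclin gene CYCB1;2 (−0.71, SE 0.15) (adjusted p = 0.0172 with an estimated correlation). DNA methylation genes fell, 8 of 20 with 0 risen, such as the methyltransferase gene CMT3 (−0.46, SE 0.12), the chromatin remodeller gene DDM1 (−0.45, SE 0.08) and AGO4 (−0.39, SE 0.07) (adjusted p = 0.000303 with an estimated correlation), and ribosomal genes fell, 12 of 21 with 0 risen, such as RPS5A (−0.58, SE 0.10) (adjusted p = 0.129 with an estimated correlation). Adjusted over the list alone, 28 cell cycle, 10 DNA methylation and 21 ribosomal genes fell. In the slide block the list means between days 10 and 15 were −1.65 for phosphate, −1.64 for auxin, 0.98 for ribosomal and 1.79 for flavonoid genes, against −1.71, −1.71, 0.85 and 1.63. Between days 15 and 20 they were −0.69 for cell cycle, −0.22 for DNA methylation and −0.57 for ribosomal genes, against −0.51, −0.19 and −0.40, and HIK (−1.21), KN (−1.13), CYCB1;2 (−0.99), CMT3 (−0.64), DDM1 (−0.57), AGO4 (−0.46) and RPS5A (−0.67) lost their calls at larger folds.

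Between days 20 and 25 auxin genes rose, 16 of 25 with 0 fallen, such as IAA29 (2.34, SE 0.50), HB-2 (2.23, SE 0.37) and GH3.5 (1.88, SE 0.28) (adjusted p = 0.579 with an estimated correlation). Cell wall genes rose, 11 of 23 with 0 fallen, such as the xyloglucan-modifying TCH4 (2.74, SE 0.85), XTH18 (2.11, SE 0.69) and XTH24 (1.41, SE 0.35) (adjusted p = 0.276 with an estimated correlation). Root markers rose too, 6 of 21 with 0 fallen and a mean of 0.25, a call lost in the slide block at 0.30 (adjusted p = 0.655 with an estimated correlation). The clock list passed as lower with a mean of −0.34 but a median of 0.17, with 4 genes risen and 7 fallen (adjusted p = 0.591 with an estimated correlation). Between days 25 and 30 jasmonate genes fell, 10 of 21 with 0 risen, such as JAZ1 (−3.06, SE 0.54) and MYC2 (−2.20, SE 0.35) (adjusted p = 0.212 with an estimated correlation). Salicylic acid genes fell, 7 of 24 with 0 risen, such as GRX480 (−2.57, SE 0.76), WRKY46 (−2.52, SE 0.38) and CBP60G (−2.46, SE 0.40), and cell cycle genes rose, 15 of 28 with 0 fallen, such as HIK (0.78, SE 0.16) and CYCB1;1 (0.61, SE 0.12) (adjusted p = 0.404 for each with an estimated correlation). DNA methylation genes rose, 7 of 20 with 0 fallen, such as CMT3 (0.50, SE 0.12) and the histone methyltransferase gene KYP (0.32, SE 0.08) (adjusted p = 0.00964 with an estimated correlation). Adjusted over the list alone, 17 auxin genes and 6 root markers rose and 1 root marker fell between days 20 and 25; between days 25 and 30, 15 jasmonate and 10 salicylic acid genes fell and 18 cell cycle and 10 DNA methylation genes rose. In the slide block the list means between days 20 and 25 were 1.00 for auxin and 0.74 for cell wall genes, against 1.01 and 0.67, and TCH4 (2.61) lost its call. Between days 25 and 30 they were −1.19 for jasmonate, −0.91 for salicylic acid, 0.40 for cell cycle and 0.18 for DNA methylation genes, against −1.23, −0.94, 0.33 and 0.19, and GRX480 (−2.26), HIK (0.90), CYCB1;1 (0.72), CMT3 (0.63) and KYP (0.36) lost their calls.

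The step between days 10 and 15 had the most changed genes, 5454 risen and 6120 fallen of 23318. Between days 4 and 6, 3156 rose and 3362 fell; between days 6 and 10, 2377 rose and 1548 fell; between days 15 and 20, 753 rose and 1164 fell. Between days 20 and 25, 2700 rose and 2883 fell, and between days 25 and 30, 1633 rose and 1599 fell. With median centring, risen genes were 74.8% of calls between days 6 and 10, against 60.6%, 26.6% between days 15 and 20, against 39.3%, and 23.5% between days 25 and 30, against 50.5%. With Agilent's processed signals they were 27.7% between days 15 and 20 and 71.0% between days 25 and 30. With the slide as a fixed block 2716, 1227, 8356, 152, 1664 and 393 genes passed in the 6 steps in order of age. In that block 59.9% of calls had risen between days 15 and 20 and 22.6% between days 25 and 30, and with terms for the batches of cRNA synthesis 54.5% and 22.3%.

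**Figure D2:**
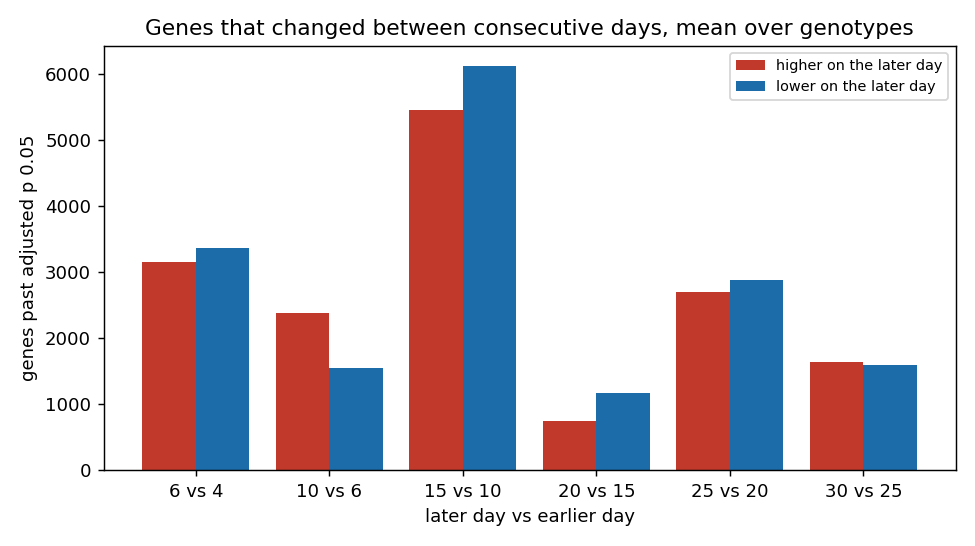
Number of genes, of 23318 tested, that were higher (red bars) or lower (blue bars) on the later of 2 consecutive days after sowing at an adjusted p under 0.05, as means over the 4 genotypes. The step from day 10 to day 15 had the highest counts, 5454 risen and 6120 fallen, and that from day 15 to day 20 the lowest, 753 and 1164.

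By the planned error, the parental difference changed with age for 1080 genes, with 669 slopes upward (61.9%) and 411 downward per 10 days. Without day 4 only 168 genes passed. That day is an end of the slope, and its array of Col-0 over C24 had the largest residual SD (0.263). No test here excluded chance for this trend. The upward share was 47.9% without the 4 arrays of highest signal, 50.1% without these, the Cy3 pair of Col-0 x C24 of day 30 and the C24 pool of day 10, and 71.7% without background subtraction. Relative to C24, Col-0 gained ARGAH2, an arginase gene (2.31 per 10 days, SE 0.41, adjusted p = 0.00501), ESM1 (1.70, SE 0.21, adjusted p = 0.000883) and AT5G26290 (1.58, SE 0.28). It lost the glucanase gene BG3 (−1.87, SE 0.37), PCR1 of the plant cadmium resistance family (−1.86, SE 0.44) and AT1G13470 (−1.62, SE 0.38). Floral promoters trended downward in Col-0 relative to C24, with 3 of 12 genes passing (adjusted p = 0.000340 with an estimated correlation), and so did the clock, with 2 of 19 (adjusted p = 0.0210 with an estimated correlation). Salicylic acid genes trended downward with 3 of 24 (adjusted p = 0.152 with an estimated correlation). Root and seed storage markers trended upward with 1 gene passing each and means of 0.20 and 0.28 (adjusted p = 0.50 for each with an estimated correlation). In the slide block these were 0.20 and 0.16, and the latter lost its call. Adjusted over the list alone, 6 floral promoters, 6 clock genes, 14 salicylic acid genes, 2 root and 4 seed storage genes passed. With the array error carried through the loop 550 genes passed, the 6 named ones among them, and with the slide as a fixed block 2, ESM1 (1.82) among the named. In that block ARGAH2 stood at 2.28, AT5G26290 at 1.39, BG3 at −1.62, PCR1 at −1.67 and AT1G13470 at −1.54. There the list means were −0.03 for floral promoters, which lost their call, −0.17 for the clock and −0.53 for salicylic acid genes, against −0.17, −0.19 and −0.59.

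By the planned error, the departure of the hybrids from the midparent changed with age for 1957 genes. Of these, 1148 were upward (58.7%, and 48.6% with the slide as a fixed block) and 809 downward. Without day 30, an end of the slope, limma called 0, with 3826 at an unadjusted p under 0.05. ARGAH2 (1.18 per 10 days, SE 0.29), the kinase gene CIPK20 (0.84, SE 0.19) and AT3G46370 (0.83, SE 0.14) trended upward, and ESP (−0.97, SE 0.29), IGMT2 (−0.96, SE 0.25) and the glutaredoxin gene GRXS13 (−0.80, SE 0.23) downward. Light harvesting genes trended upward, 9 of 37 with 1 downward and a mean of 0.11, a direction that median centring turned to a mean of −0.05 and the mean of all probes to −0.04 (adjusted p = 0.779 with an estimated correlation). The salicylic acid list trended downward with no member passing (adjusted p = 0.686 with an estimated correlation). Seed storage genes trended upward with no member passing and a mean of 0.18, and 0.61 in the slide block (adjusted p = 0.779 with an estimated correlation). Only these 3 of the 7 lists that passed are described, and 5 of 9 for the parents. With the array error carried through the loop 422 genes passed, of the named ones only AT3G46370, and with the slide as a fixed block 451, of the named ones only GRXS13 (−1.31). In that block ARGAH2 stood at 0.48, CIPK20 at 0.77, AT3G46370 at 0.68, ESP at −1.09 and IGMT2 at −0.76, with list means of 0.14 for light harvesting and −0.33 for salicylic acid genes, against 0.11 and −0.34. With limma after median centring 0 passed, with 2055 at an unadjusted p under 0.05, and without the pair of arrays with Col-0 x C24 of day 30 in Cy3 452 passed.

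On single days, where p-values measure technical spread, the parents differed at 7150 genes on day 10 (3221 higher in Col-0) and at 803 on day 6. The hybrids departed from the midparent at 4555 genes on day 30 (2678 higher), with 1182 on day 4, 946 on day 10, 315 on day 20, 251 on day 25, 11 on day 6 and 6 on day 15. The hybrids differed from each other at 1815 genes on day 10 (948 higher in Col-0 x C24), and at 0 genes on days 6 and 15 by limma, with 688 and 900 at an unadjusted p under 0.05. With the same-day arrays alone the parents differed at 5969 genes on day 10, the hybrids departed at 3526 on day 30, and the hybrids differed at 1028 on day 10. Days 6, 15 and 25 had no same-day arrays and median standard errors of 0.203 to 0.204 between the parents, against 0.127 to 0.133 on the other days, so their counts cannot be ranked with the others. Without the pair of arrays with Col-0 x C24 of day 30 in Cy3, the hybrids departed at 85 genes on day 30. With median centring they departed at 76 on day 30 and 79 on day 10, and the parents differed at 1289 on day 10 and 1544 on day 20. With the slide as a fixed block the hybrids departed at 348 on day 30, 519 on day 10 and by limma 0 on day 4 (3874 at an unadjusted p under 0.05). Of 348 daily counts under other settings, 131 moved by more than 1.5 times.

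Some pools stood apart over 282 genes higher in Col-0 by at least 1.5 on the log2 scale on days 20 and 30. The median of these genes in C24 was −0.35 on day 10, against −1.21 on day 6 and −1.12 on day 15, and in Col-0 it was 0.85 on day 10. In Col-0 x C24 it was 0.82 on day 30, against 0.78 in Col-0 and 0.44 in C24 x Col-0. Without the C24 pool of day 10, 1144 genes departed from the midparent over all days by the planned error, which leaves out the shared array error.

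**Figure D3:**
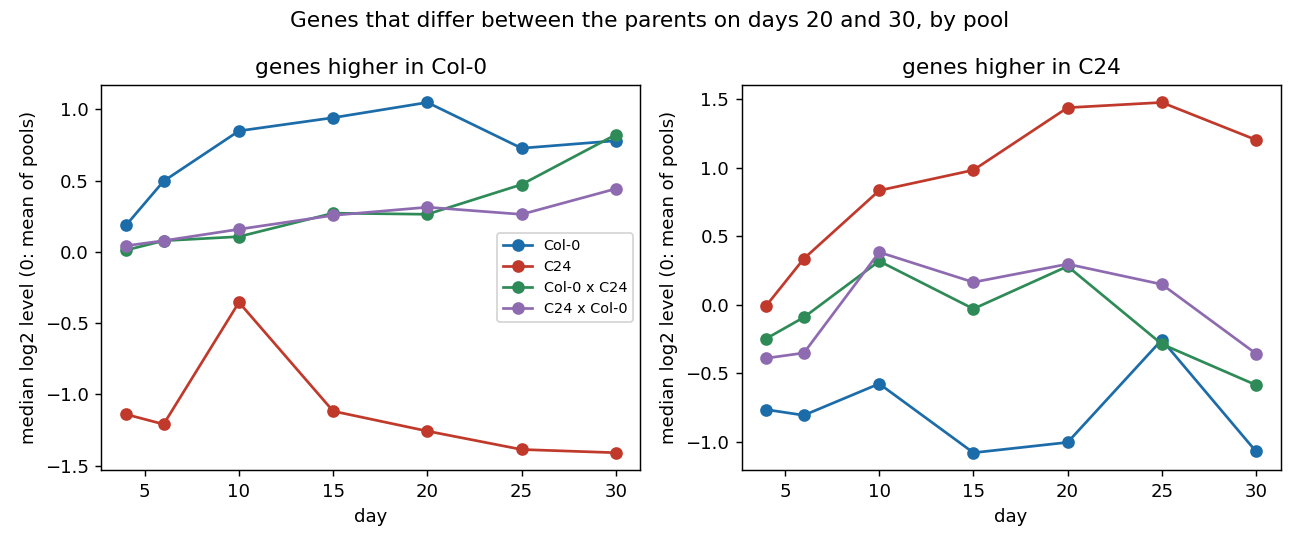
Median log2 expression relative to the mean of all pools against days after sowing, with 1 point per pool and 1 line per genotype, of 282 genes higher in Col-0 (left) and 177 higher in C24 (right), chosen on days 20 and 30. The C24 pool of day 10 lay at −0.35 over the genes higher in Col-0, and the Col-0 x C24 pool of day 30 at 0.82. The Col-0 pool of day 25 lay at −0.25 over the genes higher in C24.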

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

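Of the tests in this part, those of a mixed pool, of a change with age shared by all genotypes or found in C24 alone, and of a dye effect were chosen only after the result was seen.

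Single days stood far from the other 6 days for 12 of 67 genotype comparisons of named genes, 8 of them on day 10, where chance singles out about 5% of groups. In the difference of Col-0 minus C24, SADHU1-1 stood at 1.83 on day 10, against 4.89 to 5.90 on the other days. ESP stood at −3.11 on day 25, against −7.07 to −5.83, PR2 at 0.66 on day 4, against −4.17 to −2.27, FRI at −0.52 on day 25, against −0.39 to −0.31, and MAF5 at −1.55 on day 25, against −0.73 to −0.40. In the departure of the hybrids from the midparent, the lowest day was day 10 for CP12-2 (0.22), scpl42 (0.076), AT1G60010 (−0.12), RPS15AD (0.029), AT5G42825 (0.16), AT5G45490 (0.046) and AT5G52420 (0.0074). Among 122 comparisons of days, 1 genotype stood apart in 8, where chance again singles out about 5%. The named genes were measured in the same pools, and PS2 and IPS1 count in both steps that hold the Col-0 pool of day 10. These comparisons are therefore not independent, and neither 12 of 67 nor 8 of 122 can be weighed against 5%. CYP83A1 from day 4 to day 30 stood at 4.64 in C24, against 5.45 to 5.54 in the others. From day 6 to day 10, PS2 (4.21, against 2.27 to 2.36) and IPS1 (2.41, against 2.00 to 2.07) stood apart in Col-0 and TGG2 in C24 (1.60, against 2.71 to 2.94). From day 10 to day 15, PS2 (−3.93, against −2.32 to −2.02) and IPS1 (−2.77, against −2.05 to −1.93) stood apart in Col-0 and SRG3 in Col-0 x C24 (−2.12, against −3.52 to −3.34). KYP from day 25 to day 30 stood at 0.16 in Col-0 x C24, against 0.36 to 0.38.

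Day 10 coincided with a shift of the C24 pool of that day towards Col-0. Over the 282 genes higher in Col-0 the pool was raised by 0.97 on the array against day 6 and by 0.65 on that against day 15, days not used to choose these genes, and over the 177 genes higher in C24 it was lowered against days 6 and 15, relative to the other genotypes, by a median of −0.25 (quartiles −0.49 and 0.016), as RNA of Col-0 or a hybrid in the pool would give. In C24 itself these 177 genes were not lowered, at 0.34, 0.84 and 0.98 on days 6, 10 and 15. The relative fall thus rests on higher levels in the other genotypes on day 10, such as −0.09, 0.32 and −0.03 in Col-0 x C24. Compressed ratios were argued against by the other genes, whose change from day 10 to day 15 in C24 had a slope of 1.11 on that of the other genotypes. A change with age could not be excluded: the genes higher in Col-0 moved from day 6 to day 10 by 0.82 in C24, by 0.36 in Col-0, by 0.0066 in Col-0 x C24 and by 0.082 in C24 x Col-0, and nothing in 1 pool separates a change of C24 alone from a mixed pool. A mixed pool is therefore a candidate explanation that stays open beside a change of C24 with age.

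On day 30 the Col-0 x C24 sample in Cy3 read like Col-0, and over all genes the ratio of C24 over that sample had a slope of 0.773 on the ratio of C24 over Col-0, against 0.519, 0.128 and 0.460 on days 4, 10 and 20. Another sample in the tube would give a slope near that of Col-0 itself, and a hybrid between its parents a lower one; the value lay between the limits set for these and decided neither. A dye effect of the genes higher in Col-0 that all days share would give the sums of ratios around the genotype loops 1 sign, but they were −1.20, 0.24, 0.37 and −0.71 on days 4, 10, 20 and 30, the last 1.91 times the larger of days 10 and 20 in size. These genes were chosen on the Col-0 over C24 arrays of days 20 and 30, which are terms of the sums of those days. Selection thus pushes the sums of days 20 and 30 upward and biases the 1.91, so they do not decide on a dye effect. Day 30 lay below 0 in spite of it, and day 10, not used to choose the genes, above 0. Dominance of Col-0 alleles would raise the sample in both colours, but in Cy5 it stood at 0.03 against C24 x Col-0, which stood at −0.51 against Col-0. The gap between the colours is the loop sum of −0.71. Only day 4 gave a sum further from 0, and its loop held the Col-0 and C24 array with the highest signals. The other array with that Cy3 sample set it against Col-0 x C24 of day 4 and stood at −1.16 over these genes. Arrays of the same days and colours stood at −0.05 in Col-0, 0.05 in C24 and −0.02 in C24 x Col-0. The limits set above were not met, so the explanations stay open.

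Among genes at least 2-fold higher in Col-0, mismatches of C24 transcripts to probes might lower the C24 signal, since the accession differs from the array's reference. Second probes away from the first gave the same direction past the threshold for 99 of 137 genes (72.3%), against 49 of 63 (77.8%) among genes higher in C24. The shares did not settle whether mismatch contributes (Fisher's exact test, one-sided p = 0.259). With the array error carried through the loop 91 and 44 passed. From first to second probes the median went from 1.41 to 0.76 for genes higher in Col-0 and from −1.39 to −0.94 for genes higher in C24. The larger loss among genes higher in Col-0 is the direction that mismatch would give, but it was not tested. A difference in mRNA could give the 72.3% seen by a further probe and is a hypothesis for those genes.

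Differences between genotypes that changed with age were singled out by the test of their slope. For the parents these were 1080 genes (168 without day 4), with ARGAH2 (2.31 per 10 days), ESM1 (1.70), AT5G26290 (1.58), BG3 (−1.87), PCR1 (−1.86) and AT1G13470 (−1.62) named. For the hybrids these were 1957 genes, with ARGAH2 (1.18), CIPK20 (0.84), AT3G46370 (0.83), ESP (−0.97), IGMT2 (−0.96) and GRXS13 (−0.80) named. Without day 30 limma called 0 for the hybrids, with 3826 at an unadjusted p under 0.05. Outside the genes tested, 4210 probes that name no single locus were well above background in at least 1 pool.

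Other splits of the pools were tested for each count. For the parents 1 of 64 splits, the real one, gave 7981 genes or more (highest other 5817), for the reciprocal hybrids 1 of 64 gave 4 (highest other 2), for the hybrids against the midparent 2 of 100 gave 488 (highest other 927), and for the trend of the hybrids 1 of 100 gave 1957 (highest other 94). These splits exchange the genotypes day by day under the planned error, which breaks up the array error that the pools of a loop share, so chance in the form of that error cannot be excluded by them. With it carried, 4888, 1, 8 and 422 genes passed. For the trend of the parental difference 9 of 64 gave 1080 or more, with 6332 as the highest other. A split that exchanges the parents from some age on turns a constant difference into a trend, so its count can exceed the real one by construction. These splits therefore do not measure chance for this trend, and chance is not excluded. For comparisons of days the 8 splits, of which 1, the real one, gave as many, are too few for a share under 0.05. The real and highest other counts were 7935 and 1 for day 30 against day 4, 6518 and 1 for days 4 to 6, 3925 and 1931 for days 6 to 10, 11574 and 193 for days 10 to 15, 1917 and 0 for days 15 to 20, 5583 and 231 for days 20 to 25, and 3232 and 1 for days 25 to 30.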

How the results depend on the processing

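The 8 alternatives chosen only after the data were seen were those without the 4 arrays of highest signal, without the C24 pool of day 10, without the pair of Cy3 arrays of Col-0 x C24 of day 30 and without all of these, the linear and the log2 midparent of daily differences, the array error carried through the loop, and list means from the arrays of 1 slide; where no cause is given, the cause was not tested. Of 4905 values of named genes under other settings, 4491 kept their direction and call, 413 lost the call and 1 turned; of 9884 with 1 array, day or genotype left out, 9600 kept both and 284 lost the call. Of 2582 list values 2276 kept both, 293 lost the call and 13 turned, and of 5142 with 1 left out 4921 kept both, 220 lost the call and 1 turned. Of 297 counts 95 moved by more than 1.5 times, and of 591 with 1 left out 62 did. The cold, flavonoid and salicylic acid lists of the parents kept direction and call in 24 of 25 settings, with a lowest mean of 1.07 for cold and means of 0.80 to 1.65 and −1.55 to −0.82 for the others, and lost the call only with an estimated correlation. The 24 settings reuse the same arrays and the preset correlation, so they are not independent tests. Aquantile scaling leaves the ratios as they are by construction and tests nothing. Its 201 gene values and 105 list values are among those that kept both. Array weights ran from 5.9e-06 to 12.4 in a fit that stopped before it converged. Dim spots limit small ratios: in Cy3 between 58.7% and 99.9% of spots per array were well above background.

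With Agilent's processed signals 801 genes departed from the midparent, 8 differed between the hybrids, 2996 changed from day 15 to 20, and the trends had 651 (parents) and 3508 (hybrids). Without background subtraction the hybrids had 998 and their trend 3986, and the values of the series table gave 928, 3824 and, between the hybrids, 10. Median centring gave 3095 for the parents, 154 for the hybrids, 5024 for day 30 against day 4, and 1230, 993, 5710, 334, 1334 and 822 for the steps in order of age, with 98 and 0 for the trends. It turned the cell cycle (−0.12) and ribosomal (−0.28) lists between the hybrids, light harvesting from day 4 to 30 (−0.42), and from day 20 to 25 chlorophyll (−0.21), ribosomal (−0.37) and light harvesting (−0.40), and in the trend of the hybrids light harvesting (−0.054), which the mean of all probes turned too (−0.040). The strict filter gave 203 for the hybrids and 537 for the trend of the parents, and put RPS15AD at −0.12, because another probe then stood for the gene.

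The slide as a fixed block gave 4898 for the parents, 2640 for the hybrids, 2 between the hybrids, 2804 for day 30 against day 4, 2716, 1227, 152, 1664 and 393 for the steps other than day 10 to 15, and 2 and 451 for the trends. These counts used the planned error, without the array error carried. As a random block, with a correlation of 0.00375, the slide moved no count of a single day. Batch terms for cRNA synthesis gave 13715 for the parents, 8450 between the hybrids, 4079 for day 30 against day 4, 376, 3561 and 822 for the last 3 steps, and 60 and 96 for the trends. These terms raised the array variance of the parents 6.13 times and that between the hybrids 5.08 times, which the pool fit does not see. With the array error carried as well, limma called 2444 for the parents, 0 between the hybrids (2228 at an unadjusted p under 0.05), 0 for the hybrids (1396) and 23 and 0 (2024) for the trends.

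Array weights gave 765 for the hybrids, and pools weighted by hybridisations 2128 from day 25 to 30. The array error alone gave 106 for the hybrids, 2 between them, 6719, 4202, 8478 and 6305 for the steps other than the first and day 10 to 15, and 1857 for the trend of the parents. Same-day arrays alone gave 3195 for the parents and by limma 0 for the hybrids, between the hybrids and for both trends, with 1553, 202, 2423 and 4093 at an unadjusted p under 0.05, with fewer arrays by construction. There the cell cycle list turned between the hybrids (−0.021), and the seed storage list in the trend of the parents (0.039) turned only relative to the other genes, which its test compares it with. Time loops alone gave 5051 for day 30 against day 4 and 3878, 1418, 473, 2841 and 992 for the steps other than day 10 to 15. Days in pots alone gave 197 for the hybrids and 3015 for their trend, and turned the trends of cell cycle genes in the parents (−0.030) and of seed storage genes in the hybrids (−0.083). A minimum of 2-fold left, by construction, 729, 36, 2 and 1193 genes in the 4 main comparisons, 563, 644, 2041, 64, 488 and 440 in the steps, and 51 and 1 in the trends.

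Without the 4 arrays of highest signal the hybrids had 304, the difference between them 2, and day 25 to 30 had 2121. Without the C24 pool of day 10 the hybrids had 1144. Without the pair of Cy3 arrays the trend of the hybrids had 452, and its cold list turned (−0.0079). Without all of these the hybrids had 1016, the difference between them 2, day 6 to 10 2158, and the trends 2355 and 688. The array error carried through the loop gave 4888, 8 and 1 for the parents, the hybrids and the difference between them, and 550 and 422 for the trends. The linear midparent gave 0 for the hybrids by limma (3740 at an unadjusted p under 0.05) and 395 for their trend, and the log2 midparent in that fit 71 and 361.

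With 1 array, day or genotype left out, the parents ranged from 6186 (day 20) to 9322 (Col-0 over C24 of day 4), and the step from day 10 to 15 from 9383 to 11810. Day 30 against day 4 ranged from 4318 (Col-0 x C24) to 10405, with 5164 without C24 x Col-0. Day 4 to 6 ranged from 3292 (C24 x Col-0) to 7354, with 4143 without Col-0, and day 6 to 10 from 1268 (C24 x Col-0) to 4968, with 2000 without C24 and 1589 without Col-0 x C24. Day 20 to 25 ranged from 2749 (C24 x Col-0) to 6462, with 3460 without Col-0 x C24. Day 15 to 20 ranged from 445 (C24 x Col-0) to 3752 (C24 x Col-0 of day 20 over 15), with 946, 980 and 736 without Col-0, C24 and Col-0 x C24, and 1093 and 1159 without C24 x Col-0 of day 25 over 20 and of 15 over 10. Day 25 to 30 ranged from 241 (C24 x Col-0) to 5398 (C24 of day 30 over 25), with 1869 and 1727 without C24 and Col-0 x C24, and 1623 without C24 x Col-0 of day 30 over 25.

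The hybrids against the midparent ranged from 167 (day 30) to 2079 (C24 over Col-0 x C24 of day 20). Without days 6, 10, 15, 20 and 25 they had 253, 784, 169, 219 and 244. Without arrays over days they had 298 (C24, 20 over 15), 262 (C24, 30 over 25), 294 (C24, 10 over 6), 325 (Col-0, 30 over 25), 262 (Col-0, 6 over 4), 322 (C24 x Col-0, 6 over 4) and 213 (Col-0 x C24, 30 over 25). Without arrays of 1 day they had 965, 1486 and 739 (C24 x Col-0 over Col-0 of days 4, 10 and 20) and 1019 (C24 over Col-0 x C24 of day 10). The difference between the hybrids ranged from 2 to 7 (Col-0 x C24 over C24 x Col-0 of day 20), with 2 without C24 of day 25 over 20, C24 of day 30 over 25 and each of days 6, 15, 20 and 25; its jasmonate list ranged from −0.42 to 0.0047, the latter without the same array of day 20. The trend of the parents ranged from 168 (day 4) to 2058 (Col-0 over C24 of day 30), with 1647 without that array of day 10, 694 without Col-0 x C24 of day 30 over 25, and 355, 719 and 403 without days 6, 20 and 25. The trend of the hybrids ranged by limma from 0 (day 30, 3826 at an unadjusted p under 0.05) to 4055 (C24 x Col-0 of day 4 over 30). It had 3240 without C24 of day 4 over 30, 1243, 703 and 1181 without Col-0 of day 30 over 25, Col-0 x C24 of 30 over 25 and C24 x Col-0 of 25 over 20, 1016 without C24 over Col-0 x C24 of day 30, and 762 and 347 without days 6 and 25. No paired analysis was possible on replicate numbers, because each genotype and day had 1 pool; genotypes were paired by day, which was a term of each genotype comparison.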

Other observations

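The array error carried through the loop was added after the data were seen. None of the other tests in this part was chosen after its result was seen, but the single genes were named after their values were seen. Some groups not described above differed between the parents without a shared direction. Of the floral repressors, 5 rose and 4 fell in Col-0 against C24 and 3 did not pass (adjusted p = 0.785 for the list), and with the array error carried through the loop 4 rose and 4 fell. MAF1, a relative of FLC, was higher in Col-0 by 2.87 (SE 0.36), as were SVP (0.73), MAF2 (0.47) and MAF3 (0.26), while MAF4 (−1.21) and MAF5 (−0.73) were lower; with the slide as a fixed block the call of MAF5 was lost (−0.66). Of the glucosinolate genes, 6 rose, 9 fell and 14 did not pass (adjusted p = 0.380), and with that error carried 4 rose and 7 fell. AOP2, which makes alkenyl glucosinolates, was lower in Col-0 (−3.40, SE 0.40), as was MAM3, which elongates methionine (−1.94), and FMOGS-OX3 (2.28) and AOP1 (0.89) were higher. The single genes named here also passed with that error carried.

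The clock and chlorophyll lists did not pass between day 4 and day 30 but held genes that moved both ways. Of the clock genes, 10 rose, 5 fell and 4 did not pass. Of the chlorophyll genes, 6 rose, 7 fell and 4 did not pass, and their median was −0.21 while their mean was 0.21. Between the parents, the clock list had a median of −0.02 and a mean of 0.03, the floral promoters −0.01 and 0.15, and leaf senescence 0.06 and −0.12, none of which passed.

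One hypothesis concerned the organelle genes. Of the 4 genes that differed between the hybrids, 3 were encoded in organelles, and if organelles come from the parent named first, the difference between the hybrids could follow that between the parents. Over 108 genes encoded in organelles (56 chloroplast and 52 mitochondrial), the reciprocal difference had a slope of 0.302 (95% interval 0.205 to 0.399) on the parental difference, against 0.0176 over nuclear genes. The slope lay between 0.25, under which the hypothesis was to be dropped, and 0.5, over which it was to be kept, so it stays open. Genes of an organelle share their transcripts and are not independent replicates.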
